A study of Homo sapiens with 2 samples.

How the data were processed

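RNA was measured in 2 libraries of CHME3, an immortalised human cell line labelled as microglia, 1 from untreated cells and 1 from cells given muscarinic receptor antagonists at 5 µg/ml, a dose the labels describe as the EC50. The labels do not name the compound or the length of exposure. Per the labels, total RNA was made into TruSeq libraries and read on an Illumina HiSeq instrument. Each sample was placed in its group by its treatment label. With 1 library per condition no difference has a replicate check, and any interval computed on fragments compares these 2 libraries, not the conditions.

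Per the submitters' processing notes, TopHat and Cuffdiff were used with the build hg38, and no version is given there. Every line of both deposited files names Cufflinks as its source and carries a RefSeq transcript. The FPKM values that the authors deposited are per reference transcript and are other than plain counts: they are fragments divided by effective transcript length and by sequencing depth. The authors' files also hold lower and upper bounds of each FPKM and a score per transcript relative to its major isoform, and the score was not used. Both files list the same 56891 transcripts of 26370 gene names. Transcripts encoded by mitochondrial DNA are not in these files, so the list of them holds 0 genes. Coordinates are those of the files, on hg38. The labels do not say whether the libraries keep strand, so reads of a gene and of an overlapping neighbour cannot be told apart.

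FPKM values were summed over the transcripts of a gene. The main measure was log2 of (treated FPKM + 1) over (untreated FPKM + 1), which understates the ratio of genes with low values. Genes entered where the mean of the 2 libraries was at least 1 FPKM. A gene was counted as different when this measure was at least 2-fold in either direction, a rule of size with no test.

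The fragments behind a value were recovered from the authors' bounds as the square of 2 × FPKM divided by the distance from FPKM to the upper bound. Among genes with 1 transcript and at least 3 fragments, 21.1% of 5931 untreated and 21.3% of 5992 treated values were whole within 0.01 fragments, so these are estimates, not counts. From whole values of at least 10 fragments on transcripts of at least 1000 bases, a line of fragments per FPKM on length gave a depth of 6727524 fragments in the untreated and 7298953 in the treated library. For genes with several transcripts the fragments were estimated from FPKM, length and this depth. In single-transcript genes with at least 20 fragments, the estimate was a median of 1.01 times the recovered number in both libraries. Intervals of an FPKM ratio are 95% exact conditional binomial intervals on rounded fragments. They cover counting error only, and leave out how fragments were divided between isoforms or copies of a gene and PCR duplicates.

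Before the data were examined, 41 gene lists, the rule for named genes and the alternative settings were fixed, apart from those named as added. For each list the median log2 ratio of members over the floor was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list was called outside random lists when its percentile was below 2.5 or above 97.5. The 35 lists with at least 5 members over the floor got a percentile, 10 lay outside, and 1.75 would do so by chance if genes were independent. Random lists treat genes as independent, so genes regulated together make a percentile look more extreme than it is. Older gene symbols and biotypes were matched through a RefSeq gene table of GRCh38.

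The genes named are the protein-coding genes with a mean of at least 5 FPKM and transcripts of at least 300 bases that passed 2-fold (at most 15 each way), every muscarinic receptor, up to 4 members over the floor with the largest absolute log2 ratio of each list described or of cell type markers, up to 2 members of lists within random lists, and the 5 genes with the highest values in each library. Other genes named were chosen after their values were seen, and are marked so. A gene that the rule takes is withheld and not reported here.

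The 2-fold rule was tested on simulated data, with libraries drawn from the fragments of the 11668 genes and 50 genes given each true fold. The changed genes were taken only from those with a mean of at least 5 FPKM and transcripts of at least 300 bases. Among these the rule called 0 genes at a true fold of 1.5, 94% at 2.5, and all 50 at 4 and at 0.25. The rates do not apply to 2-fold genes with lower values or shorter transcripts. Of 400 simulated lists of 25 unchanged genes, taken from the same genes, 6.5% fell outside the central 95% of random lists. All of 100 lists shifted by 0.3 lay above it. Smaller shifts, such as the medians of the called lists other than interferon, were not simulated. The simulated libraries held counting noise alone and the lists were drawn at random, so the 6.5% does not apply to lists of genes regulated together.

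Alternatives were other pseudocounts, floors and scalings, protein-coding genes alone, the transcript with the highest mean, a demand that the authors' bounds of the libraries do not overlap, other folds, and 10 or 50 bins. Added after the data were seen were fragments in place of FPKM, removal of transcripts under 300 bases or of genes under 20 fragments, and removal of trends with GC content and length in 10 bins each. GC content came from transcripts of GENCODE release 29. Overlapping genes were found by position, and near-identical copies as genes that share at least 25% of the 31-base words of a transcript, a rule also chosen after the data were seen. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.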

Results

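The series measured messenger RNA in 2 cultures of CHME3, an immortalised human cell line that the labels call microglia, under a title that concerns factors for microglial survival. There was 1 library of untreated cells and 1 of cells given muscarinic receptor antagonists, compounds that block a family of acetylcholine receptors. The depth recovered from the deposited bounds was an estimated 6727524 fragments in the untreated and 7298953 in the treated library. At least 1 FPKM was listed for 11637 genes in the untreated and 11652 in the treated library. The highest values belonged to genes of translation, glycolysis and the cytoskeleton. RPS18, a ribosomal protein, was at 4468 and 4734 FPKM in the untreated and treated libraries, GAPDH, a glycolytic enzyme, at 4119 and 4329, and EEF1A1, a translation elongation factor, at 3699 and 3630.1. RPS27 and RPL8 completed the highest 5 of the untreated library, and TMSB10 and ACTB, of the actin cytoskeleton, those of the treated library. Pairs of values for a gene are given below in the order untreated and treated, in FPKM, and coordinates are on hg38.

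The comparison asked which genes differ between treated and untreated cells. The libraries were closely alike, and the gene group that lay farthest from random lists was that of interferon-induced genes, which were higher in the treated library. Of 11668 genes with a mean of at least 1 FPKM, 97.8% lay within 1.5-fold. Across these genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.971 and Spearman's rho 0.977. Pearson's r was 0.993 across the 11604 of them with transcripts of at least 300 bases. The median log2 ratio of treated over untreated for all 11668 genes was 0.00, with quartiles of -0.10 and 0.11. The libraries also differed in listed 18S ribosomal RNA, a difference that goes with every gene group below because each condition has 1 library. RNA18S5, the gene name of this RNA, has 7 transcript records, which on chromosome 21 span 8209631 to 8438744. Summed over them, RNA18S5 was at 363 and 759 FPKM, a ratio of 2.09 with a 95% counting interval of 2.01 to 2.17, and had more fragments than any other 2-fold gene. RNA28S5, the 28S ribosomal RNA, was at 456 and 504 FPKM, a ratio of 1.10 (1.08 to 1.13). RNA45S5, their precursor, was at 10.5 and 10.6 FPKM, a ratio of 1.01 (0.926 to 1.11), which includes 1. These 3 genes were named after their values were seen. Their ranges on chromosome 21 overlap, and the intervals leave out how reads were divided among these records.

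Few protein-coding genes with a mean of at least 5 FPKM differed by 2-fold. Among 8059 such genes with transcripts of at least 300 bases, 3 were higher and 1 was lower in the treated library. APOC1, an apolipoprotein (chromosome 19, 44914664 to 44919349), was at 10.3 and 2.94 FPKM from 19 and 6 fragments, a log2 ratio of -1.52 and an FPKM ratio of 0.285 (0.0931 to 0.742), where the bracket gives the 95% counting interval. H3F3A, which encodes histone H3.3 (chromosome 1, 226062707 to 226072002), was at 7.43 and 20.7 FPKM, a ratio of 2.79 (1.68 to 4.80). Most of the signal at this locus was listed under the overlapping pseudogene record H3F3AP4, named after its values were seen, and both records together summed to 333 and 312 FPKM. C9orf116 (chromosome 9, 135495180 to 135499915) was at 4.42 and 10.7 FPKM, a ratio of 2.42 (1.33 to 4.60). MSMP, a secreted microseminoprotein (chromosome 9, 35752991 to 35754277), was at 2.72 and 7.46 FPKM from 8 and 26 fragments, a ratio of 2.75 (1.21 to 7.02), and overlaps the gene RGP1, named after its values were seen.

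Over all 11668 genes, 41 were at least 2-fold higher and 36 at least 2-fold lower in the treated library. Transcripts under 300 bases, such as microRNA precursors and small nucleolar RNAs, made up 20 of the higher and 25 of the lower genes. Of these 45 genes, 40 were listed at 0 in a library and 42 rested on at most 3 fragments over both libraries. SNORD55, a small nucleolar RNA chosen after its value was seen, was listed at 0 in the untreated library and at 1536 FPKM in the treated library, the latter from 1 fragment. Protein-coding genes with longer transcripts made up 12 of the higher and 4 of the lower genes.

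**Figure D1:**
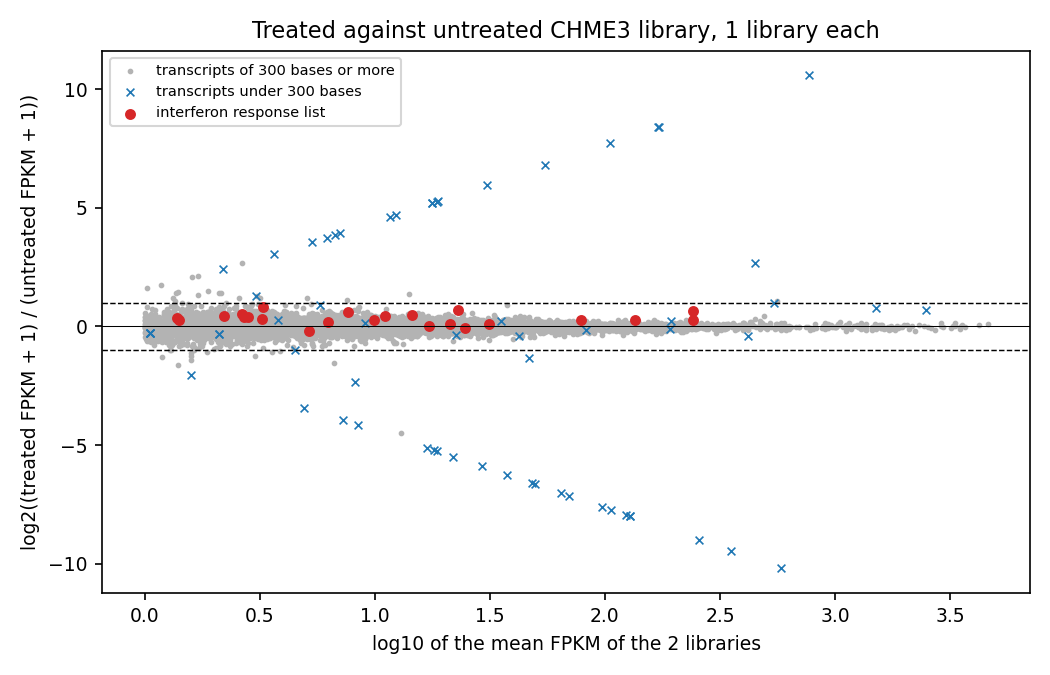
Each point is a gene with a mean of at least 1 FPKM, with log10 of its mean FPKM on the x axis and its log2 ratio of treated over untreated on the y axis, 1 library each, and dashed lines at 2-fold. Genes with transcripts under 300 bases make up 45 of the genes at or beyond the lines, and the interferon response list lies mostly above 0 and within them.

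Interferon response genes were higher in the treated library as a group. Their median log2 ratio was 0.33 over 23 members, above all of 10000 random lists, whose central 95% ran from -0.07 to 0.08. Of the 23 members 21 were higher and 2 lower, 4 were at least 1.5-fold higher, and 0 reached 2-fold with the pseudocount of 1. The counting interval of the FPKM ratio lay above 1 in 12 members and below 1 in 0. Such intervals also often excluded 1 elsewhere, above in 16 and below in 3 of 31 cytoskeleton genes, and above in 3 and below in 24 of 53 ribosomal protein genes. Genes varied between the libraries by more than counting. At 300 to 1000 fragments over both libraries the interquartile width of log2 ratios was 0.188, against 0.150 in simulated counting. MX2, an interferon-induced GTPase (chromosome 21, 41362023 to 41408942), was at 2.06 and 4.48 FPKM, an FPKM ratio of 2.17 (1.48 to 3.25). Its neighbour MX1, an antiviral GTPase (chromosome 21, 41420558 to 41459214), was at 17.6 and 28.6 FPKM, a ratio of 1.63 (1.41 to 1.88). IFI6, an interferon-induced membrane protein (chromosome 1, 27666061 to 27672213), was at 186 and 297 FPKM, a ratio of 1.60 (1.46 to 1.74). IFIT3, an interferon-induced protein with tetratricopeptide repeats (chromosome 10, 89327819 to 89340968), was at 5.89 and 9.41 FPKM, a ratio of 1.60 (1.23 to 2.08), but its most abundant transcript alone had a log2 ratio of -0.06. The lower members were the transcription factors IRF1, at 5.62 and 4.75 FPKM, and IRF9, at 25.2 and 24.2, both named after their values were seen and both with intervals that include 1. The chemokines CXCL10 and CXCL11, also named after their values were seen, were listed at 0 in both libraries.

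**Figure D2:**
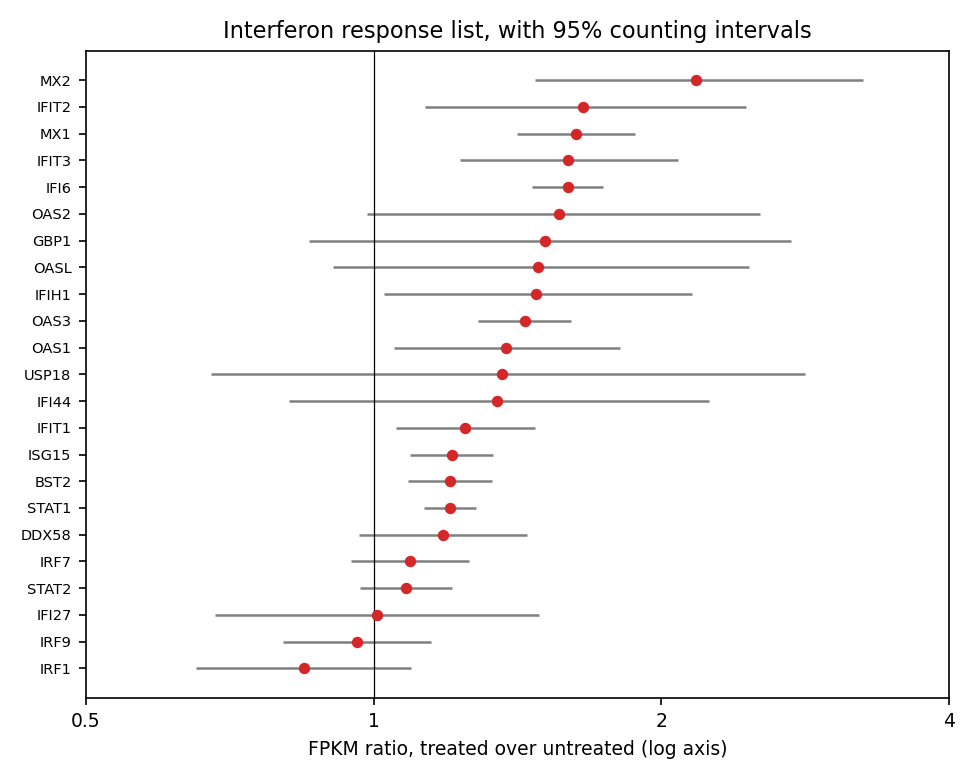
FPKM ratio of treated over untreated (log axis) for the 23 members of the interferon response list with a mean of at least 1 FPKM, with 95% counting intervals as lines, 1 library per condition; members beyond the named genes are shown after their values were seen. The highest ratio is that of MX2 at 2.17, and 12 intervals lie above 1.

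Judged against random lists, genes of glycolysis, the extracellular matrix and the cytoskeleton were slightly higher in the treated library. The interval of the list's own median, across members that are not replicates, held only positive values for glycolysis (0.0244 to 0.121) and the cytoskeleton (0.0252 to 0.129). For the matrix list it ran from -0.000925 to 0.103 and so spans both signs. The glycolysis and hypoxia list had a median log2 ratio of 0.08 over 29 members, at percentile 99.97 of random lists, with 23 members higher and 6 lower. CA9, a carbonic anhydrase induced in hypoxia, was at 1.83 and 2.99 FPKM from 17 and 30 fragments, with a counting interval of the ratio that includes 1, ALDOC, an aldolase, at 29.4 and 35.1, and ADM, the peptide hormone adrenomedullin, at 41.5 and 46.8, while HIF1A, the oxygen-regulated transcription factor, was at 56.9 and 47.3. Extracellular matrix and fibroblast markers had a median of 0.08 over 23 members, at percentile 99.77, with 16 higher and 7 lower. This call was lost where the authors' bounds do not overlap, at percentile 59.8. TAGLN, an actin-binding protein, was at 397 and 498 FPKM, a log2 ratio of 0.32, TIMP1, an inhibitor of matrix proteases, at 128 and 151, FN1, fibronectin, at 2725 and 3021, and COL6A2, a collagen VI chain, at 112 and 124. Cytoskeleton and adhesion genes had a median of 0.05 over 31 members, at percentile 99.14, with 22 higher and 9 lower. TUBA1A, an alpha tubulin, was at 111 and 134 FPKM, FLNA, which crosslinks actin, at 397 and 459, MYL6, a myosin light chain, at 973 and 1119.9, and RHOB, a small GTPase, at 23.4 and 19.7. The proteasome list lay at the edge of the central band, with a median of 0.04 over 31 members at percentile 97.55, 18 higher and 13 lower. It fell inside the band under 7 of 16 alternative settings. The interval of its median, -0.0405 to 0.0548, spans both signs. PSMC2 was at 24.7 and 30.8 FPKM, PSMC4 at 32.0 and 36.1, PSMB2 at 23.9 and 26.8 and PSMA6 at 85.2 and 74.7.

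Judged against random lists, immediate early, cholesterol, ribosomal protein and mitosis genes were slightly lower in the treated library. The interval of the list's own median, across members that are not replicates, held only negative values for immediate early genes (-0.156 to -0.00568). The same held for ribosomal protein genes (-0.0686 to -0.0250) and mitosis (-0.0923 to -0.0122). For the cholesterol list the interval ran from -0.177 to 0.00274 and so spans both signs. Immediate early genes, which respond rapidly to stimuli, had a median log2 ratio of -0.10 over 24 members, at percentile 0.09, with 18 lower and 6 higher. FOS, a subunit of the transcription factor AP-1, was at 16.8 and 9.62 FPKM, a ratio of 0.572 (0.459 to 0.711), and KLF2, a zinc finger transcription factor, at 11.4 and 6.71, a ratio of 0.591 (0.432 to 0.804). KLF6 was at 37.2 and 31.4 FPKM and BTG2, an antiproliferative factor, at 6.44 and 5.43. The list of cholesterol synthesis and uptake had a median of -0.07 over 25 members, at percentile 1.215, with 17 lower and 8 higher. INSIG1, which restrains sterol synthesis, was at 84.5 and 70.1 FPKM, a ratio of 0.830 (0.772 to 0.892), STARD4, a sterol transporter, at 19.7 and 16.4, MSMO1, a sterol oxidase, at 65.2 and 55.6, and TM7SF2, a sterol reductase, at 16.0 and 13.9. Ribosomal protein genes had a median of -0.05 over 53 members, at percentile 0.315, with 41 lower and 12 higher. This call was lost where the authors' bounds do not overlap, at percentile 40.4. RPL7 was at 1805 and 1627 FPKM, RPS20 at 812 and 738, RPS2 at 2836 and 2587 and RPL22 at 221 and 201. The list of mitosis and G2/M had a median of -0.05 over 34 members, at percentile 1.73, with 24 lower and 10 higher. DLGAP5, a spindle protein, was at 52.2 and 44.8 FPKM, CDK1, the kinase that drives entry into mitosis, at 134 and 116, TOP2A, a DNA topoisomerase, at 192 and 167, and AURKA, a mitotic kinase, at 197 and 172, although the most abundant transcript of AURKA alone had a log2 ratio of 0.08.

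**Figure D3:**
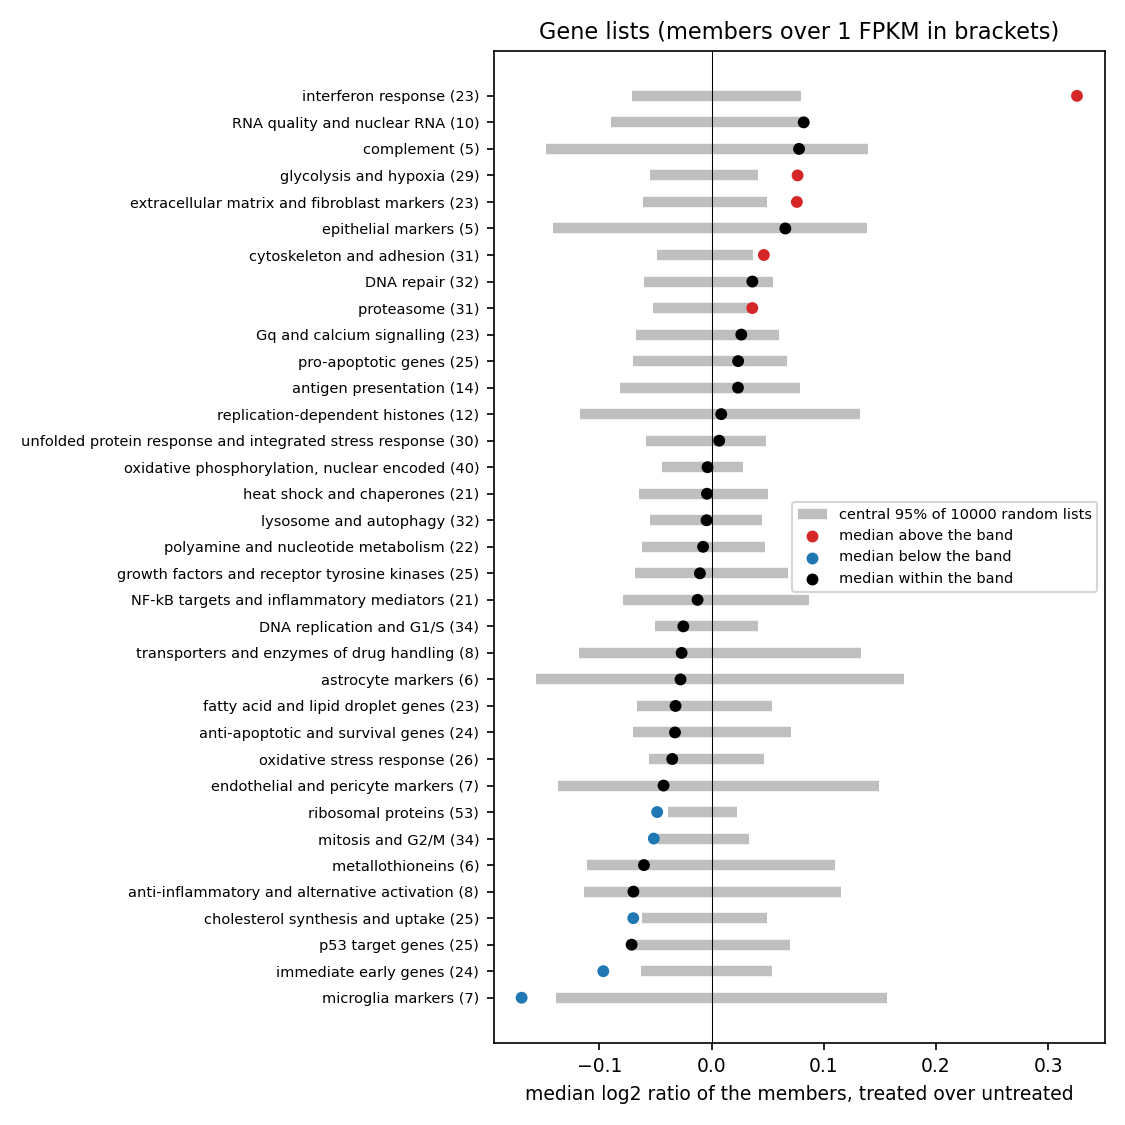
Median log2 ratio of treated over untreated for the 35 lists with at least 5 members over 1 FPKM, with the central 95% of 10000 matched random lists as bars and 1 library per condition. The interferon response list lies farthest from its bar at 0.33, and 5 lists lie above and 5 below their bars.

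The receptors that the treatment targets were at or near the limit of what these libraries can show. CHRM3, which couples to Gq, was at 0.344 and 0.320 FPKM from 6 and 6 fragments, a ratio of 0.931 (0.249 to 3.48). CHRM4, which couples to Gi, was at 0.810 and 0.669 FPKM from 9 and 8 fragments, a ratio of 0.826 (0.277 to 2.41). CHRM1 was at 0.0292 and 0.0614 FPKM, from no more than 1 fragment in each library. CHRM2 and CHRM5 were listed at 0 in both libraries, where 3 fragments would correspond to 0.171 and 0.158 FPKM for CHRM2 and 0.155 and 0.144 for CHRM5. Of the nicotinic receptor and acetylcholine handling list, 4 of 25 genes were over the floor, too few for a percentile, with a median log2 ratio of -0.08. Its subunits CHRNA5 and CHRNB1 were at 2.64 and 1.99 and at 5.05 and 4.31 FPKM. Genes of Gq and calcium signalling had a median of 0.03 at percentile 82.1, with RCAN1, a calcineurin inhibitor, at 9.09 and 11.3 FPKM and PRKCE, a protein kinase C, at 3.57 and 4.54.

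In the main setting, genes of cell death and survival did not stand apart from random lists. Pro-apoptotic genes had a median log2 ratio of 0.02 at percentile 75.1, with 13 higher and 12 lower. Among the lower was the caspase CASP6, at 5.21 and 3.15 FPKM. With the most abundant transcript the pro-apoptotic median was 0.0893, outside the band at percentile 98.19. With fragments in place of FPKM it was -0.0247, inside the band. Anti-apoptotic and survival genes had a median of -0.03 at percentile 15.8. BCL2 was at 1.30 and 2.15 FPKM, with a counting interval of the ratio from 0.993 to 2.81, and CSF1, a growth factor for macrophages and microglia, at 3.64 and 4.95, a ratio of 1.36 (1.04 to 1.78). The p53 target list had a median of -0.07 at percentile 2.565, just inside the band, with 19 members lower and 6 higher, and 11 of 16 alternative settings placed it outside. PLK3 was at 7.97 and 6.16 FPKM, and TP53INP1 at 3.36 and 2.21, although the most abundant transcript of TP53INP1 alone had a log2 ratio of 0.16.

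Inflammatory and stress genes also lay within random lists, as did the metabolic lists other than glycolysis and cholesterol. NF-kB targets and inflammatory mediators had a median log2 ratio of -0.01 at percentile 33.3, with TNFAIP3, an inhibitor of NF-kB signalling, at 0.848 and 1.66 FPKM and the chemokine CXCL3 at 0.607 and 1.40, from 4 and 10 fragments. Antigen presentation had a median of 0.02 at percentile 73.6, with PSMB8, an immunoproteasome subunit, at 16.8 and 24.8 FPKM and HLA-DPA1 at 3.24 and 2.10. Complement genes were at percentile 89.1, with CD55, a complement regulator, at 10.3 and 13.03 FPKM, and anti-inflammatory and alternative activation genes at 11.1, with ARG2, an arginase, at 13.99 and 11.6. The unfolded protein and integrated stress response list was at percentile 65.8, heat shock genes at 52.4, oxidative stress genes at 10.6, metallothioneins at 14.5, lysosome and autophagy genes at 48.9 and fatty acid genes at 17.5. PSAT1, a serine synthesis enzyme, was at 27.2 and 35.0 FPKM, FTL, the ferritin light chain, at 2375 and 2057, ATG12, an autophagy factor, at 10.7 and 7.64, and FABP5, a fatty acid carrier, at 15.5 and 9.22. GLA, a lysosomal galactosidase, was higher, with an FPKM ratio of 1.30 (1.02 to 1.64). CPT1A, of mitochondrial fatty acid uptake, was at 2.33 and 1.45 FPKM, but its most abundant transcript alone had a log2 ratio of 0.13. Genes of DNA replication and G1/S were at percentile 18.9, DNA repair at 89.7, replication-dependent histones at 49.8, oxidative phosphorylation at 61.7, polyamine and nucleotide metabolism at 48.6, drug handling at 29.5 and growth factors and receptor tyrosine kinases at 36.8. ORC1, of the origin recognition complex, was at 17.4 and 13.1 FPKM, GINS3, of the replicative helicase, at 8.56 and 10.6, SAT1, a polyamine acetyltransferase, at 56.8 and 41.2, GDF15, a stress-induced cytokine, at 16.99 and 11.7, and IGFBP3, which binds insulin-like growth factors, at 1.39 and 2.36.

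Most markers of microglia were under 1 FPKM in both libraries, while 23 of 31 matrix and fibroblast markers had a mean of at least 1 FPKM and 5 were listed at 0 in both. Of 29 microglia markers 22 were under 1 FPKM in both libraries and 13 were listed at 0 in both. The latter include AIF1, TMEM119 and CX3CR1, named after their values were seen, for which 3 fragments in the untreated library would correspond to 0.338, 0.176 and 0.144 FPKM. The 7 markers over the floor had a median log2 ratio of -0.17 at percentile 1.31, with 5 lower and 2 higher, a call lost under 2 of 14 alternative settings. The interval of this median, -0.294 to 0.0530, spans both signs. CD68, a lysosomal protein of macrophages, was at 15.7 and 12.6 FPKM, PROS1 at 3.11 and 2.58, CD14, a lipopolysaccharide co-receptor, at 1.97 and 1.63, and MERTK, a receptor for apoptotic cells, at 2.98 and 2.54, all with intervals of the ratio that include 1. The most abundant transcript of CD14 alone had a log2 ratio of 0.73, and that of TUBB3, a tubulin of neurons, -0.09. Blood cell markers had 0 of 17 genes over the floor, neuron markers 1 of 18, TUBB3 at 29.3 and 29.9 FPKM, and oligodendrocyte markers 2 of 11, CNP at 31.4 and 33.3 and CSPG4 at 18.8 and 19.8. Astrocyte markers were at percentile 34.0, endothelial and pericyte markers at 23.4 and epithelial markers at 85.2. Of the 6 astrocyte markers over the floor 3 were higher and 3 lower, with SLC1A3, a glutamate transporter, at 3.97 and 5.25 FPKM, SOX9, a transcription factor, at 2.24 and 1.75, and FGFR3, a growth factor receptor, at 2.79 and 2.34. Of the 7 endothelial and pericyte markers 2 were higher and 5 lower, with RGS5 at 1.72 and 1.17 FPKM, ANPEP, an aminopeptidase, at 3.34 and 2.48, KCNJ8, a potassium channel subunit, at 2.30 and 1.92, and MCAM, a cell adhesion molecule, at 66.3 and 71.2. Of the 5 epithelial markers 4 were higher and 1 lower, with KRT18, a keratin of simple epithelia, at 241 and 262 FPKM and CLDN4, a tight junction protein, at 1.70 and 1.49. The RNA quality and nuclear RNA list had a median of 0.08 at percentile 97.36, inside the band, and 5 of 14 alternative settings placed it outside. Its members went both ways, among them MALAT1, a nuclear RNA named after its values were seen, at 54.5 and 40.1 FPKM, a ratio of 0.737 (0.699 to 0.777).

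**Figure D4:**
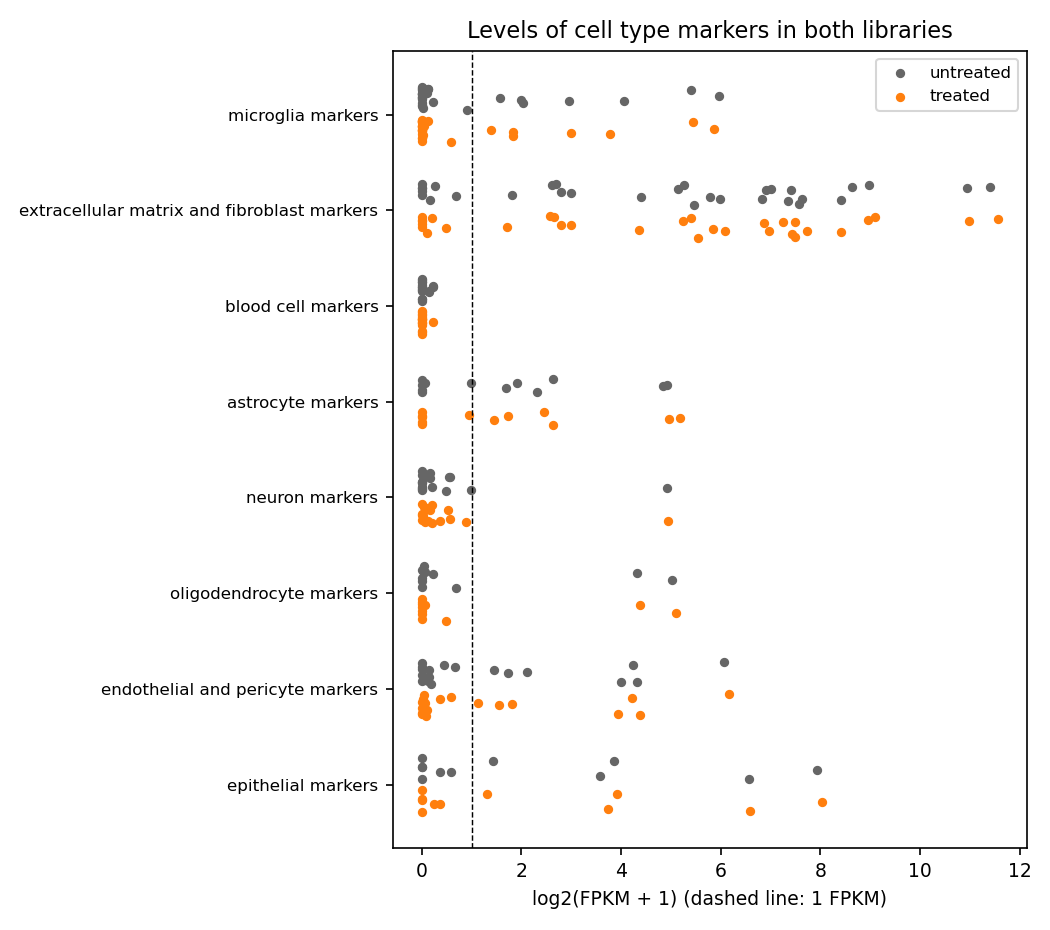
Levels of cell type markers as log2(FPKM + 1) in the untreated and the treated library, 1 point per gene and library, with scatter within a marker group added for legibility and a dashed line at 1 FPKM. Of 29 microglia markers 22 lie left of the line in both libraries, while 23 of 31 extracellular matrix and fibroblast markers have a mean of at least 1 FPKM.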

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

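Fragments in place of FPKM, removal of short or low-fragment genes and the GC and length correction were chosen after the data were seen. Each condition has 1 library, so no replicate could be left out, and no paired analysis was possible because each condition has 1 library. The counts of 2-fold genes, 41 higher and 36 lower, depended on the setting: 88 and 84 with a pseudocount of 0.1, 91 and 83 with values scaled to a fixed sum, 101 and 107 with the most abundant transcript, 12 and 4 for protein-coding genes, 8 and 4 where the authors' bounds do not overlap, 21 and 11 without transcripts under 300 bases, and 8 and 4 without genes under 20 fragments. A floor of 10 gave 15 and 20, a 1.5-fold rule 140 and 120. With a pseudocount of 5, a floor of 5 and at 4-fold there were 21, 21 and 22 higher and 24 lower genes each. Other settings left both counts within 1.5 times the main ones. The median of all genes was -0.0027 with a floor of 5, -0.0063 with a floor of 10 and 0.0139 with upper quartile scaling, against 0.0026.

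Of 162 recomputed values of the 10 lists outside random lists, 151 kept their call, and none changed side. The interferon list kept it in all 17 of its alternatives, with medians from 0.20 to 0.49. However, median ratio, upper quartile, trimmed mean and fixed-sum scaling used factors between the libraries of 0.998 to 1.01, too near 1 to test this call. The calls lost were the proteasome list with a pseudocount of 5 (0.033), with median ratio (0.0335), upper quartile (0.0485) and trimmed mean scaling (0.0346), the most abundant transcript (0.0394), fragments (0.0104) and the correction (0.0219); microglia markers with a pseudocount of 5 (-0.082) and the most abundant transcript (-0.1035); and, where bounds do not overlap, ribosomal proteins (-0.1077) and matrix markers (0.149). That demand left 2 lists outside, since most lists then had fewer than 5 genes and gave no value. Lists that came to lie outside random lists were p53 targets with pseudocounts of 0.1 (-0.091), 0.5 (-0.0748) and 5 (-0.0598), with median ratio (-0.0741), trimmed mean (-0.073) and fixed-sum scaling (-0.0735), protein-coding genes, 10 bins and 50 bins (-0.0713 each), fragments (-0.0976) and the correction (-0.077); RNA quality with a pseudocount of 5 (0.0792), floors of 5 and 10 (0.0821 each), upper quartile (0.0945) and trimmed mean scaling (0.0804); complement without a floor (0.1334) and with fixed-sum scaling (0.1976); and pro-apoptotic genes with the most abundant transcript (0.0893). Floors of 5 or 10 left several small lists without a value, and the correction was void for RNA quality, where 70% of members had a GC value. Among 997 recomputed values of named genes 8 changed sign, all with the most abundant transcript. The main counting interval excluded 1 for TP53INP1 (0.1583), CPT1A (0.1252), IFIT3 (-0.0569) and AURKA (0.0767), and included it for CD14 (0.7336), TUBB3 (-0.0942), MUC1 (-0.1033) and TIPARP (0.1218). A further 8 values moved beyond their counting interval without a change of sign. The cause was not tested.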

Other observations

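The tests of GC content and length, library scaling, list choice, drug treatment, short transcripts, partner genes and protein-coding higher genes, and the further interferon-induced genes, were chosen after the result was seen, and the simulation of counting noise over all 2-fold genes of 300 bases or more was widened after its result was seen. Further interferon-induced genes, outside the list fixed beforehand, were also higher in the treated library. Of 48 such genes the values of 7 had been seen when they were listed, so these were set aside. Of the 36 others with at least 1 FPKM, 32 were higher and 4 lower. The counting interval of the FPKM ratio lay above 1 in 13 and below 1 in 0, although genes in general varied between these libraries by more than counting. The genes named here were chosen after their values were seen. IFITM1, a membrane protein that limits viral entry, was at 36.1 and 49.7 FPKM in the untreated and treated libraries, PLSCR1, a phospholipid scramblase, at 15.9 and 19.8, and ADAR, an RNA-editing enzyme, at 64.1 and 70.4. IFNB1, IFNG and IFNL1, which encode interferons, were listed at 0 in both libraries. The receptor chains IFNAR1, at 5.50 and 6.36 FPKM, and IFNAR2, at 9.16 and 8.99, had intervals that include 1.

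Interferon response genes were higher in the treated library by a median log2 ratio of 0.33. A trend with GC content or transcript length is argued against, since the median was 0.354 (95% interval 0.26 to 0.45) once both trends were taken off. Library scaling is argued against by the median of all genes, 0.0026 (95% interval -0.000583 to 0.0056), since 1 factor would shift all genes alike and the interval of the list's median was 0.26 to 0.44. Chance in the choice of list is argued against, for these 2 libraries, by the median of 0.179 over the 36 genes not seen before, above all random lists. Interferon-induced genes can move together, so these genes are not an independent check of a difference between conditions. The drug treatment and any other difference between the 2 cultures, such as cell density or RNA preparation, cannot be told apart with 1 library per condition. That the antagonists may raise interferon-induced genes is therefore a hypothesis, which replicate cultures would test.

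The 2-fold genes with transcripts under 300 bases rested on few fragments, with a median of 1 over both libraries. In 100 simulated unchanged pairs of libraries, counting gave a mean of 9.24 higher and 8.73 lower such genes, and 0 draws reached the 20 and 25 observed. Few fragments on a short effective length therefore cannot be told apart from other sources, since the recovered fragments are below 1 for some of these genes and a simulation of whole counts describes those poorly. No biological explanation was tested.

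The 2-fold genes with transcripts of 300 bases or more numbered 32, of which 20 had fewer than 20 fragments over both libraries and 21 had a counting interval that excludes 1, a share raised by the choice of genes with large differences. Counting noise gave a mean of 20.8 such genes in 100 simulated unchanged pairs with a highest draw of 32, reached once, while an earlier form kept to genes over the floor gave a mean of 16.3 and a highest draw of 27, so by the bound written beforehand counting is argued against as the whole source, by a narrow margin. The excess lay in protein-coding genes that were higher, 12 against a simulated mean of 4.38 and a highest draw of 9. By contrast, 68 of 100 draws reached the 4 protein-coding lower genes, 18 the 9 non-coding higher and 42 the 7 non-coding lower genes. Among the non-coding genes, RNA18S5 and the pseudogene GTF2IP4 have many fragments and intervals far from 1. The simulation did not model reads divided between overlapping or near-identical genes, and some protein-coding higher genes have such partners. Summed with partners, NARR, COMMD3-BMI1, H3F3A and RGPD8 had log2 ratios of 0.056, -0.277, -0.092 and -0.056. The sums for SAPCD1 and MSMP had 0.453 and 0.671, and these genes were listed here after their values were seen. Reads divided differently between overlapping or near-identical genes cannot be told apart from other sources: 8 of 13 genes with a partner kept a sum less than 25% apart, but abundant partners fix that outcome, and of the 5 genes that could have moved the sum 1 kept it within that bound (20%, exact 95% interval 0.505 to 71.6), under a criterion revised after the result was seen. That gene is GTF2IP4, named after its values were seen, at 25.7 FPKM in the untreated and 0.191 in the treated library, whose sum with its copies was 81.8 and 81.9.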
